A study of Mus musculus with 40 samples.

How the data were processed

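Gene expression was measured in lung tissue of female wild-type (WT) C57BL/6 mice and of mice of the same strain deficient in STAT6, the transcription factor that carries signals from the interleukin-4 and interleukin-13 receptors (STAT6 KO). Per the labels, mice received 162 µg of Mitsui-7, a multiwalled carbon nanotube, in 50 µl by intratracheal instillation, or a dose of 0, and lungs were taken 1 or 28 days later. What the control animals received is not given in the sources used here. RNA came from random sections of lung, and heart and liver were removed from the same animals. Each of 40 Agilent 2-colour whole-genome arrays carried lung RNA in the red dye (Cy5) and a universal mouse reference RNA, pooled from cell lines, in the green dye (Cy3), with no array that exchanged the dyes.

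Per the file headers, spot intensity was read with Agilent Feature Extraction 11.0.1.1, which gave the signal and local background of each dye as an unnormalised intensity, and also a processed intensity after the tool's own background subtraction and dye normalisation. The LogRatio column is the log10 of red over green processed signal, per the file headers. A separate table deposited by the authors holds 1 log2 value per probe and array. Its values follow the log2 of sample over reference, with a slope against the unprocessed log2 ratio between 0.856 and 0.987, so it was read as within-array normalised by the authors with a method not given in the sources used here. The main values below were computed from the unprocessed signals, and correlated with the authors' log2 values across probes with r between 0.983 and 0.996 per array.

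Background was corrected with the normexp method of limma 3.58.1 (R 4.3.3) with an offset of 50, and each array was normalised by loess, giving log2 of lung over reference. The plan named mean signals; the deposited tables hold median spot signals, which were used instead, with median local background. The tables give transcript identifiers and no gene symbols, so probes were named by matching identifiers to the reference gene table: 28026 of 55681 probes (50.3%) matched 21154 genes. The unmatched ones, among them 16194 probes named by chromosome position and 2178 named by Ensembl transcripts, were left out of the main test. A probe was kept when its Cy5 signal was well above background on at least 4 arrays of at least 1 group. This left 30939 probes, 19940 of them matched, and the brightest probe of each gene represented it, giving 15233 tested genes. The annotation and the arrays' grid follow different genome builds, so genes are named without coordinates.

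The labels place 38 arrays in 8 groups by genotype, treatment and labelled day, 5 arrays each except the STAT6 KO control and STAT6 KO nanotube groups labelled day 1, which have 4. The other 2 arrays, both STAT6 KO labelled day 1, carry a title and a dose label that contradict each other, so they entered no comparison. The arrays lay on 6 slides, and most slides hold 1 array of each of 4 to 8 groups. One linear model with a mean per group was fitted across all genes with limma's lmFit and eBayes (30 residual and 4.33 prior degrees of freedom). From it came 10 contrasts: nanotube against control in each genotype and day, STAT6 KO against WT controls on each day, the difference of the nanotube response between genotypes on each day, and the difference of the response between days in each genotype. P-values are two-sided limma tests with Benjamini-Hochberg adjustment within a contrast, and a gene passed at an adjusted p under 0.05. Errors beside log2 changes are standard errors (SE) of that model. They rest on 1 spread per gene between the arrays of a group, pooled over all 8 groups, so groups outside a contrast also set its SE. Saa3, for one, had SDs of 0.43 and 0.16 in WT groups labelled day 1 and 3.25 in WT nanotube arrays labelled day 28. Its SE labelled day 1 carries the wider spread too. Each array was taken to be 1 animal, since the labels speak of samples per group without numbering animals. The number of arrays limits the precision. A second fit added the slide as a fixed term, and differences were also taken within each slide that held the compared groups.

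Before the data were examined, 41 gene lists were fixed (18 pathways and 23 cell types, including heart, adipose and other tissues that a lung piece could carry). Each list was tested in each contrast with limma's camera with a preset correlation of 0.01, adjusted over all 410 tests, and again with the correlation estimated from the arrays; members were also counted with p adjusted over the list alone. Genes named in the text follow a rule of the same time. The rule takes the 10 largest rises and 6 largest falls that passed and carry a proper symbol; in contrasts of a pair of groups their arrays must not overlap. It adds the 2 members of each list with the lowest adjusted p under 0.05, and a panel of 23 genes whether or not they passed, of which 22 were measured; Cxcl2 was not. Genes outside the rule are named as chosen after their values were seen. Where no array of 1 of 2 compared groups had the gene above background, a bound on the change is given. It is the mean of the brighter group less that of the dimmer one in the Cy5 channel alone, after loess and Aquantile. Values of the dimmer group below the lowest signal called above background were set to it. This bound leaves out the reference and is open to dye bias, so it can exceed the fold of the fitted ratio, which stands beside it. Genes above background on only some arrays of a group keep their fitted change.

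Alternatives tried were no background correction, the Aquantile between-array normalisation, Agilent processed signals, median centring, the Cy5 channel alone, the authors' log2 table, no filter or a stricter filter on dim probes, the mean of a gene's probes, the slide as a fixed or random term, fits of the compared groups alone, array weights, trended robust variance, a minimum change of 1.5-fold, and leaving out each array in turn. Chosen after seeing the data were a test of all kept features, a heart marker score as a covariate, and a fit without 1 doubted array. The fit and the calling of genes were tested on simulated log2 ratios in which 200 of the 15233 genes were shifted. A log2 shift of 1 was recovered in 83.6% to 100% of genes depending on the contrast, and a shift of 0.5 in 46.3% to 82.1%. The simulated noise was independent between genes and had 1 spread per gene in all groups, unlike the arrays. These shares may therefore be too high for real genes. Background correction, normalisation and the choice of probes were not tested this way. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.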

Results

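Lung RNA was profiled on 40 arrays, 38 of which the labels place in 8 groups. Labelled day 1, these were WT control (n = 5), WT nanotube (n = 5), STAT6 KO control (n = 4) and STAT6 KO nanotube (n = 4); labelled day 28, the same kinds of group held 5 arrays each. Between 51.2% and 69.1% of spots stood above background in the sample dye, with a median signal of 102 to 159, and no spot was saturated. Values are log2 ratios of lung over reference RNA, and a change is the difference of a pair of group means. The series title asks whether STAT6 signalling, rather than interleukin-1, carries the fibrotic response of the lung to carbon nanotubes.

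Stat6 itself was lower in STAT6 KO lung. Its brightest probe averaged -0.363 (SD 0.233, n = 18) in STAT6 KO arrays and 0.555 (SD 0.227, n = 20) in WT arrays, and the ranges overlapped slightly, from -0.936 to -0.001 and from -0.021 to 0.825. Within each slide every STAT6 KO array lay below every WT array. Among controls the difference was -0.83 ± 0.15 (SE, adjusted p = 0.00517) labelled day 1 and -0.97 ± 0.14 (adjusted p = 0.000266) labelled day 28. The call labelled day 1 was lost without STAT6 KO control replicate 1 (-0.74, adjusted p = 0.062) or replicate 3 (-0.77, adjusted p = 0.0501). With a slide term it held (-0.776, adjusted p = 0.000122). With median centring the differences labelled day 1 and day 28 (-0.82 and -1.07) no longer passed (adjusted p = 0.983 and 0.0591). The other probes of the gene were also lower in STAT6 KO, at -0.113 (SD 0.144) against 0.129 (SD 0.171) and at -0.763 (SD 0.152) against -0.263 (SD 0.189). All remained above background, and whether any of them lies in the deleted part of the gene is not known here; a probe outside it checks nothing.

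**Figure D1:**
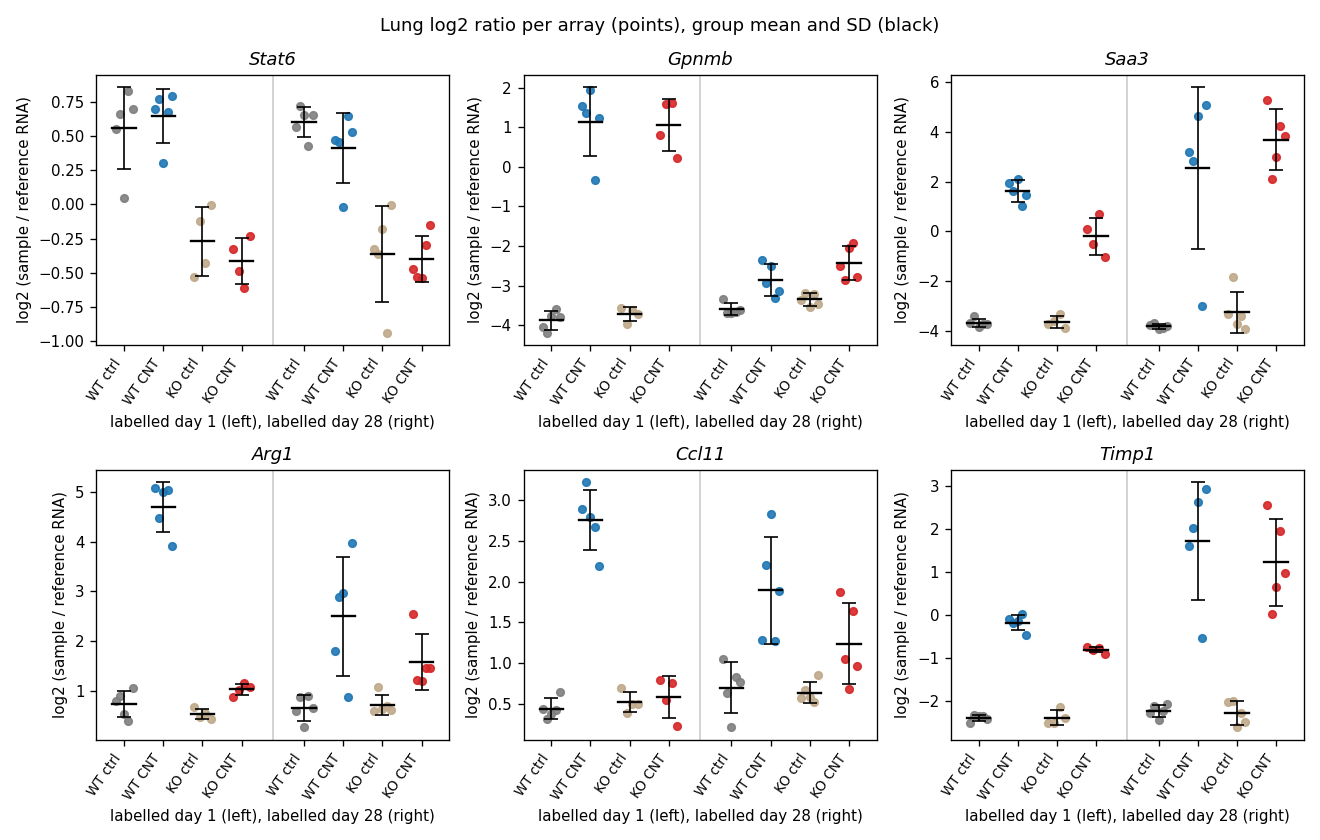
Log2 ratio of lung over reference RNA (vertical axis) for 6 genes in every array of the 8 groups (horizontal axis); points are arrays, black bars the group mean and SD, ctrl control and CNT nanotube. Saa3 and Timp1 rose in all 4 nanotube groups, while Arg1 and Ccl11 labelled day 1 rose in WT (by 3.96 and 2.32) and stood at 0.50 and 0.06 in STAT6 KO, neither of which passed.

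The WT response labelled day 1 addresses what the instilled nanotubes do to normal lung. Its largest change was in Saa3, a serum amyloid of the acute phase, which rose by 5.30 ± 0.79 (adjusted p = 2.33e-06, n = 5 per group), from -3.68 (SD 0.16) to 1.62 (SD 0.43). Next to it stood genes of loaded phagocytes: Gpnmb, a lysosomal glycoprotein of macrophages, rose by 5.02 ± 0.27 (adjusted p = 4.76e-16) and Trem2, a lipid-sensing receptor, by 4.39 ± 0.18 (adjusted p = 2.06e-19). Genes that interleukin-4 and interleukin-13 induce rose to a like extent, among them Arg1, which breaks down arginine, by 3.96 ± 0.32 (adjusted p = 7.92e-12). The chitinase-like Chil4 rose by 3.92 ± 0.29 and Chil3 by 3.54 ± 0.38, and the goblet-cell gene Clca1 by 4.39 ± 0.99 (adjusted p = 0.000664). Across the lung 2666 of 15233 genes rose and 2553 fell.

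Of the 30 measured members of the phagocyte lysosome and lipid list, 28 rose and none fell (29 and 0 adjusted over the list alone), with a median of 1.82. The call held with an estimated correlation (adjusted p = 0.00515). Beside Gpnmb and Trem2 stood the proton pump subunit Atp6v0d2 (3.11 ± 0.21) and the collagen-degrading protease Ctsk (2.14 ± 0.14). The macrophage elastase Mmp12 was not above background in controls and rose at least 14.1-fold in Cy5 signal alone (10.84-fold in the fitted ratio, adjusted p = 2.02e-17). Among 26 IL-4/IL-13 macrophage genes 18 rose and 1 fell (18 and 2 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation), with a median of 1.01. Of 22 type 2 epithelium and mucus genes 13 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 0.271 with an estimated correlation). The list was led by the anion exchanger Slc26a4 (4.30 ± 0.30), the ion transport regulator Fxyd4 (3.95 ± 0.29), the lectin Itln1 (3.89 ± 0.48, with 1 of 5 controls above background) and the airway mucin Muc5ac (1.69 ± 0.26).

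Chemokines and inflammatory mediators rose as well. Of 16 CC chemokines 11 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.193 with an estimated correlation). Ccl9 rose by 3.72 ± 0.22, the eosinophil attractants Ccl24 by 2.59 ± 0.51 and Ccl11 by 2.32 ± 0.22, and the monocyte attractant Ccl2 by 2.01 ± 0.44. Acute phase genes counted 11 rises among 20 members and no fall (12 and 0 adjusted over the list alone; adjusted p = 0.368 with an estimated correlation), among them the iron-binding Lcn2 (2.05 ± 0.14). Of 26 TNF, IL-6 and NF-kB genes 15 rose and none fell (16 and 0 adjusted over the list alone; adjusted p = 0.454 with an estimated correlation). Il6 rose by 1.41 ± 0.38, with 2 of 5 controls above background, and Tnf by 0.89 ± 0.20. IL-1 family signalling showed 13 rises and 1 fall among 21 genes (15 and 1 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). The alarmin Il33 rose by 2.00 ± 0.20, while Il1b, at 0.87 ± 0.35, did not pass (adjusted p = 0.0532) but did with a slide term (0.99, adjusted p = 0.0217). Neutrophil chemoattractants had 6 rises and 1 fall among 13 (6 and 1 adjusted over the list alone; adjusted p = 0.334 with an estimated correlation), and Cxcl1 rose by 1.58 ± 0.48, with 2 of 5 controls above background. Neutrophil markers showed no shift as a list: 5 of 22 rose and 3 fell (5 and 3 adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.625).

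Complement genes rose in 14 of 20 cases (14 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation), C3 by 1.83 ± 0.17. Cell cycle genes rose in 19 of 45, with no fall (19 and 0 adjusted over the list alone; adjusted p = 0.588 with an estimated correlation), at a median of 0.28. Monocyte and interstitial macrophage markers counted 14 rises and 2 falls of 21 (14 and 2 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation), with Ms4a7 at 2.97 ± 0.15. Alveolar macrophage markers counted 11 rises and 2 falls of 20 (11 and 2 adjusted over the list alone; adjusted p = 0.316 with an estimated correlation). Among profibrotic mediators 10 of 26 rose and 4 fell (10 and 4 adjusted over the list alone; adjusted p = 0.193 with an estimated correlation). They include the growth factor Igf1 (3.19 ± 0.19), the matrix protein and cytokine Spp1 (3.71 ± 0.23) and the protease inhibitor Timp1 (2.22 ± 0.38). Of 41 collagen and matrix genes 10 rose and 5 fell (12 and 5 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.115). Of the fibrillar collagens of scar tissue, Col3a1 rose by 0.76 ± 0.17 and Col1a1 by 0.39 ± 0.15 (adjusted p = 0.0433), a call lost without any 1 of 6 arrays.

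Markers of several structural cell types fell. Endothelial markers fell in 12 of 23 and rose in none (12 and 0 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation), with the endothelin receptor Ednrb at -1.13. Smooth muscle markers fell in 8 of 13 (9 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation), with the contractile protein Cnn1 at -1.26 ± 0.19. Fibroblast markers fell in 9 of 21 (11 adjusted over the list alone; adjusted p = 0.334 with an estimated correlation), with the growth factor receptor Pdgfra at -0.82 ± 0.09. Club cell markers fell in 8 of 18 (9 adjusted over the list alone; adjusted p = 0.325 with an estimated correlation). Alveolar type 2 markers rose in 10 of 19 (10 adjusted over the list alone; adjusted p = 0.271 with an estimated correlation). Heart muscle markers moved beside these groups, with a median of -1.45, 8 falls and 1 rise, that of the protease Corin (1.82 ± 0.17, with 2 of 5 controls above background), among 16 (9 and 1 adjusted over the list alone; adjusted p = 0.73 with an estimated correlation). Within slides their median ran from -1.98 to -0.26. Of the heart genes among the largest falls Myl4, at -2.12 ± 0.83, and Tnnt2, at -1.82 ± 0.68, no longer passed with a slide term (adjusted p = 0.0677 and 0.0589). Ckmt2, a creatine kinase of heart and skeletal muscle, stood at -1.96 ± 0.69 and cannot be told apart from the heart genes here. The other large falls were the lectin Asgr1 (-2.16 ± 0.16), the lactonase Pon1 (-2.06 ± 0.21) and the sulfotransferase Sult1d1 (-1.75 ± 0.37). Adipose markers did not pass as a list (median -0.49, camera adjusted p = 0.123).

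In all, 26 of 41 lists were called in this contrast, all 26 also with a slide term and 1 of them with an estimated correlation. With the slide as a term 2888 genes rose and 2880 fell. On the 4 slides that hold both groups 97.3% to 99.3% of called genes kept their sign. Arrays did not overlap for 3517 genes (23.1%), where chance gives 0.794%. Setting each array's median to 0 moved the median of all genes by 0.118 and left 2546 called genes, 82.6% of them rises in place of 51.1%.

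The same comparison in STAT6 KO lung asks how much of this response runs without STAT6. The largest changes were in phagocyte genes: Gpnmb rose by 4.77 ± 0.30 (adjusted p = 1.25e-13, n = 4 per group), Trem2 by 4.15 ± 0.20 and Spp1 by 3.58 ± 0.25. Saa3 rose by 3.44 ± 0.88 (adjusted p = 0.00523), and Mmp12, not above background in controls, rose at least 11-fold in Cy5 signal alone (8.381-fold in the fitted ratio). Several panel genes known to answer to IL-4 and IL-13 did not pass: Arg1 changed by 0.50 ± 0.36 (adjusted p = 0.407), Chil3 by 0.38 ± 0.43 (adjusted p = 0.643), and Ccl11 by 0.06 ± 0.25 (adjusted p = 0.918). Ccl24 stood at 0.07 ± 0.57 (adjusted p = 0.96), Muc5ac at 0.53 ± 0.29 (adjusted p = 0.234) and Clca1 at 0.84 (adjusted p = 0.698). Ccl17 stood at 0.62 (adjusted p = 0.0621, and 0.042 with a slide term), while Retnla, a resistin-like gene usually counted with such genes, rose by 0.73. In total 1439 genes rose and 1063 fell.

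Lysosome and lipid genes rose in 25 of 30 and fell in 1 (27 and 1 adjusted over the list alone), with a median of 1.68, and this call held with an estimated correlation (adjusted p = 0.0035). Complement rose in 13 of 20 (14 adjusted over the list alone; adjusted p = 0.064 with an estimated correlation), C1qb by 1.59. Cell cycle genes rose in 20 of 45 (29 adjusted over the list alone; adjusted p = 0.335 with an estimated correlation). Monocyte and interstitial macrophage markers rose in 12 of 21 and fell in 1 (14 and 1 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation). Acute phase genes rose in 8 of 20 (12 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation), with Lcn2 at 1.59 ± 0.16. TNF, IL-6 and NF-kB genes rose in 12 of 26 (12 adjusted over the list alone; adjusted p = 0.374 with an estimated correlation), with Tnf at 1.01 ± 0.22. IL-1 family signalling genes rose in 7 of 21 (7 adjusted over the list alone; adjusted p = 0.321 with an estimated correlation), and Il1b, at 0.73, did not pass (adjusted p = 0.231). Of 16 CC chemokines 6 rose (9 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). Ccl9 rose by 3.18 ± 0.25, while Ccl2 stood at 1.31 ± 0.49 and did not pass (adjusted p = 0.0634). IL-4/IL-13 macrophage genes rose in 7 of 26 and fell in 1 (10 and 2 adjusted over the list alone; adjusted p = 0.374 with an estimated correlation), at a median of 0.32. Members that passed included the scavenger receptor Msr1, which was not above background in any control and rose at least 3.69-fold in Cy5 signal alone (3.24-fold in the fitted ratio). Type 2 epithelium and mucus genes rose in 5 of 22 and fell in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.483 with an estimated correlation). Slc26a4 rose by 2.47 ± 0.33 and Fxyd4 by 1.84 ± 0.33.

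Collagen and matrix genes passed as a list here, with 11 rises and 3 falls among 41 (14 and 3 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). Col3a1 rose by 1.02 ± 0.19, Col1a1 by 0.57 ± 0.17 (adjusted p = 0.0161) and fibronectin, Fn1, by 1.15. The call of Col1a1 was lost without nanotube replicate 2 (adjusted p = 0.058) or control replicate 2 (adjusted p = 0.0533). Plasma cell markers rose in 5 of 12 and fell in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation), with the antibody joining chain Jchain at 2.15 ± 0.29. Endothelial markers fell in 11 of 23 (11 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation). Smooth muscle markers fell in 5 of 13 (9 adjusted over the list alone; adjusted p = 0.316 with an estimated correlation). Large single falls were the acetylcholinesterase anchor Colq (-1.71 ± 0.29), the glutathione transferase Gsta2 (-1.67), the natriuretic peptide receptor Npr3 (-1.61), the endothelial Esm1 (-1.55), Pon1 (-1.50) and the BMP inhibitor Smad6 (-1.49). Heart muscle markers had a median of 0.05 and did not pass (camera adjusted p = 0.833), with within-slide medians from -0.84 to 1.44. With a slide term 1649 genes rose and 1300 fell. Within slides 98.9% to 99.6% of called genes kept their sign, and arrays did not overlap for 21.9% of genes (chance gives 2.86%). Median centring left 835 called genes, 82.8% of them rises in place of 57.5%.

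Whether the genotypes differ was tested on the difference of their responses. Labelled day 1, the STAT6 KO response was lower for Chil4 (-3.77 ± 0.44, adjusted p = 1.58e-06), Arg1 (-3.46 ± 0.48, adjusted p = 7.21e-05) and Chil3 (-3.17 ± 0.57, adjusted p = 0.00344), with 5 WT and 4 STAT6 KO arrays per treatment. Ccl11 was lower too (-2.26 ± 0.33, adjusted p = 0.000161). Awat1 (-2.46 ± 0.27, adjusted p = 4.2e-07) and the retinol carrier Rbp4 (-2.27 ± 0.21, adjusted p = 2.2e-08) were also lower. So were the arginine transporter Slc7a2 (-1.09 ± 0.17), the chemokine Ccl6, the goblet-cell protease Capn9 (-1.38), the lysosomal protease Ctsl (-1.11) and the collagenase Mmp13 (-1.02). For Capn9 and Mmp13, 1 control array per genotype was above background. In total the response of 26 genes was lower and that of 1, the synaptic adhesion gene Lrrc4b, higher (0.66 ± 0.13, adjusted p = 0.013). With Agilent processed signals Chil4 (adjusted p = 0.105), Arg1 (0.237), Ccl11 (0.149), Slc7a2 (0.194) and Capn9 (0.0926) no longer passed, nor did Ccl6, Mmp13 and Lrrc4b. Other type 2 genes did not pass, namely Clca1 (-3.55, adjusted p = 0.429), Ccl24 (-2.52, adjusted p = 0.259) and Muc5ac (-1.16, adjusted p = 0.313), nor did Saa3 (-1.86, adjusted p = 0.662). The SE of Clca1, 1.48, carries the wide spread of its WT groups labelled day 28 (SD 2.94 and 3.11). Spp1 (-0.13), Col1a1 (0.18) and Col3a1 (0.26) did not pass either.

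Among the lists, IL-4/IL-13 macrophage genes had a lower response in STAT6 KO (median -0.54), with 4 of 26 members passing (11 adjusted over the list alone). This was the call of the contrast that held with an estimated correlation (adjusted p = 0.0488). On the slides that hold all 4 groups the median was -0.615 and -0.558. Lower by a called camera test were also the lysosome list (median -0.34, 1 of 30 members passing, 6 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation) and type 2 epithelium and mucus genes (-0.46, 3 of 22, 7 adjusted over the list alone; adjusted p = 0.271 with an estimated correlation). CC chemokines were lower as well (-0.38, 2 of 16, 3 adjusted over the list alone; adjusted p = 0.298 with an estimated correlation), as were alveolar macrophage markers (-0.33, 1 of 20, 4 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation). Profibrotic mediators stood at -0.14 with no member passing (2 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation). The response of interferon genes was higher in STAT6 KO (median 0.28, no member passing, 3 adjusted over the list alone; adjusted p = 0.368 with an estimated correlation). Heart muscle markers differed by 1.57 (adjusted p = 0.549 with an estimated correlation). With a slide term 1 gene was higher and 29 lower. Agilent processed signals gave 14 genes, the strict filter on dim probes 16 and array weights 49.

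Across the 15233 genes the changes of both genotypes correlated with r = 0.791 (jackknife SE 0.0448 over arrays; genes are not independent replicates, and each genotype has its own controls). Risen in both were 1248 genes, where independent calls would give 251.8, and fallen in both 843, where independent calls would give 178.2, while 3 moved in opposite directions. Both contrasts use the same spread per gene, so their calls are not independent and these expected counts may be too low.

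**Figure D2:**
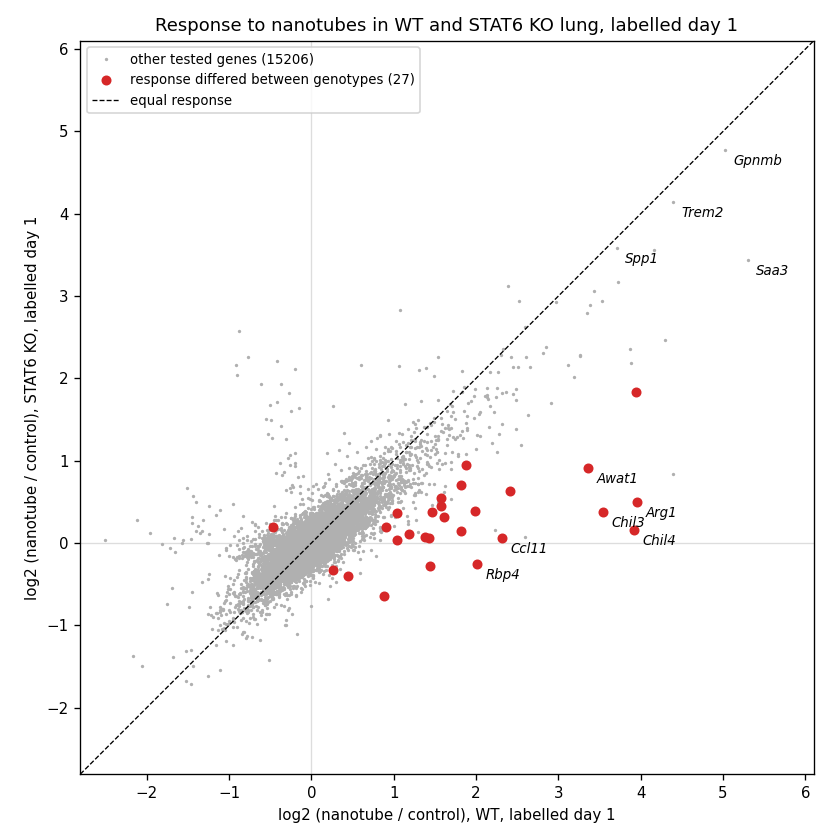
Log2 change with nanotubes labelled day 1 for 15233 genes (points), WT on the horizontal and STAT6 KO on the vertical axis; red points are the 27 genes whose response differed between genotypes and the dashed line marks equal response. The changes correlated with r = 0.791, Gpnmb (5.02 and 4.77) lies near the line, and Arg1 (3.96 and 0.50) and Chil4 lie far below it.

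Labelled day 28, the largest changes in WT lung were in acute phase, chemokine and cytokine genes. Saa3 rose by 6.37 ± 0.79 (adjusted p = 1.23e-06, n = 5 per group), although 1 of the 5 nanotube arrays stood at -3.01, near the controls (mean -3.82, SD 0.10). Without that array Saa3 rose by 7.76 ± 0.45, Ccl7 by 4.40, Ccl2 by 3.87, Cxcl1 by 3.73 and Ccl24 by 3.71; without replicate 5 Saa3 rose by 5.73. With all arrays Timp1 rose by 3.97 ± 0.38, the monocyte attractants Ccl7 by 3.76 ± 0.45 and Ccl2 by 3.23 ± 0.44. The metal-binding Mt2 rose by 3.34 ± 0.39, the neutrophil attractant Cxcl1 by 3.01 ± 0.48 and the fever cytokine Il6 by 2.60 ± 0.38 (with 2 of 5 controls above background). Among type 2 genes Ccl24 (3.09 ± 0.51), Slc26a4 (2.40 ± 0.30), Arg1 (1.84 ± 0.32, adjusted p = 9.87e-05), Ccl11 (1.20 ± 0.22) and Muc5ac (1.02 ± 0.26) rose. Chil3 (-0.02, adjusted p = 0.979) and Clca1 (1.51, adjusted p = 0.301) did not pass. Clca1 did without nanotube replicate 1 (2.67, adjusted p = 0.0241) or control replicate 1 (2.58, adjusted p = 0.0408). Its change shrank to 0.85 (adjusted p = 0.615) without nanotube replicate 2 and to 0.57 (adjusted p = 0.745) without control replicate 3. In total 1889 genes rose and 1555 fell.

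Acute phase genes rose in 13 of 20 (16 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation), with a median of 1.15. TNF, IL-6 and NF-kB genes rose in 18 of 26 with 1 fall (20 and 1 adjusted over the list alone; adjusted p = 0.275 with an estimated correlation), among them the endotoxin co-receptor Cd14 (1.64). Neutrophil markers rose in 13 of 22 (15 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation) at a median of 0.75. Neutrophil chemoattractants rose in 7 of 13 with 1 fall (8 and 1 adjusted over the list alone; adjusted p = 0.334 with an estimated correlation). IL-1 family signalling counted 9 rises and 1 fall of 21 (9 and 1 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation), and Il1b rose by 2.01 ± 0.35. CC chemokines counted 10 rises and 2 falls of 16 (11 and 2 adjusted over the list alone; adjusted p = 0.273 with an estimated correlation). IL-4/IL-13 macrophage genes rose in 16 of 26 (16 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation), among them the oxysterol enzyme Ch25h (2.21 ± 0.28) and the T cell attractant Ccl17 (1.42). Type 2 epithelium genes rose in 9 of 22 and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.335 with an estimated correlation), including the resistin-like Retnlb (at least 2.41-fold in Cy5 signal alone, 2.34-fold in the fitted ratio). Within-slide medians of the list ran from -0.443 to 1.53. Matrix proteases and inhibitors rose in 13 of 27 and fell in 5 (16 and 5 adjusted over the list alone; adjusted p = 0.271 with an estimated correlation).

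Collagen and matrix genes showed no shift as a list: 8 of 41 rose and 7 fell (11 and 8 adjusted over the list alone; camera adjusted p = 0.956). Its median (-0.06) and the mean (0.057) differ in sign. Among its members the proteoglycan Vcan rose by 1.24 and Tgfbi by 0.80, while Col1a1 (0.15, adjusted p = 0.551) and Col3a1 (0.44, adjusted p = 0.0559) did not pass. Col3a1 did without nanotube replicate 1 (adjusted p = 0.0359) or replicate 4 (0.0213), or without control replicate 2 (0.0109) or replicate 5 (0.0486). With any other array left out it did not. Profibrotic mediators counted 10 rises and 4 falls of 26 (11 and 5 adjusted over the list alone) and missed the threshold (camera adjusted p = 0.0548). The lysosome list rose in 9 of 30 and fell in 3 (9 and 3 adjusted over the list alone) without passing (camera adjusted p = 0.186), with Spp1 (0.49) not passing. Alveolar macrophage markers fell in 10 of 20 and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation), with the ribonuclease Ear1 at -0.96. NK cell markers fell in 7 of 16 (8 adjusted over the list alone; adjusted p = 0.434 with an estimated correlation) and T cell markers in 5 of 20 (5 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation). Fibroblast markers fell in 7 of 21 (7 adjusted over the list alone; adjusted p = 0.335 with an estimated correlation). Large single falls were the small proteoglycan Ogn (-1.44 ± 0.20), Bcan (-1.26), Colq (-1.24), Asgr1 (-1.21), Mamdc2 (-1.14) and Npr3 (-1.12). Heart markers had a median of 0.12 (camera adjusted p = 0.69; within slides -1.85 to 2.28). With a slide term 1997 genes rose and 1751 fell. Within slides 92.6% to 99.5% of called genes kept their sign; arrays did not overlap for 13% of genes against 0.794% by chance. The count was 2261 without WT nanotube replicate 5, 3906 without replicate 4, the array with low Saa3, and 752 with median centring.

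In STAT6 KO lung labelled day 28 acute phase, chemokine and cytokine genes led. Saa3 rose by 6.93 ± 0.79 (adjusted p = 1.05e-06, n = 5 per group), its relative Saa1 by 3.96 ± 0.54, and Timp1 by 3.52 ± 0.38. Ccl7 rose by 3.44 ± 0.45, Cxcl1 by 3.31 ± 0.48 (with 3 of 5 controls above background), and Ccl2 by 3.14 ± 0.44. The neutrophil attractant Cxcl5 rose by 3.08 ± 0.67 (with 2 of 5 controls above background), the interferon-induced chemokine Cxcl10 by 2.92 ± 0.35 and Il1b by 2.52 ± 0.35. Il6 rose at least 8.13-fold and Saa2 at least 8.66-fold in Cy5 signal alone (8.28-fold and 7.542-fold in the fitted ratio). Neither was above background in any control. Arg1 (0.85, adjusted p = 0.0688), Ccl11 (0.60, adjusted p = 0.0602) and Ccl24 (0.73, adjusted p = 0.363) did not pass, nor did Chil3 (-0.23), Col1a1 (0.09) or Col3a1 (0.41, adjusted p = 0.0997). Ccl11 did without nanotube replicate 3 (0.743, adjusted p = 0.0277) or replicate 5 (0.675, adjusted p = 0.0438). In total 1366 genes rose and 706 fell.

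TNF, IL-6 and NF-kB genes rose in 19 of 26 (21 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation) and acute phase genes in 13 of 20 (14 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation). Neutrophil markers rose in 15 of 22 (15 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation), with the neutrophil protein S100a8 at 2.18 ± 0.38. IL-1 family signalling genes rose in 9 of 21 and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). CC chemokines rose in 7 of 16 (10 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation). IL-4/IL-13 macrophage genes rose in 11 of 26 (13 adjusted over the list alone; adjusted p = 0.213 with an estimated correlation), among them Ccl17 (1.73 ± 0.21) and Ch25h (2.32). Type 2 epithelium genes, with 3 rises among 22 (3 adjusted over the list alone), did not pass as a list (camera adjusted p = 0.434). Nor did collagen and matrix genes, with 5 rises and 1 fall among 41 (5 and 2 adjusted over the list alone; camera adjusted p = 0.922), whose median (-0.04) and mean (0.068) differ in sign. Adipose markers fell in 3 of 10 (3 adjusted over the list alone; adjusted p = 0.328 with an estimated correlation), with the lipid droplet protein Plin1 at -1.20. Heart markers had a median of -1.17 with 1 of 16 members passing (0 adjusted over the list alone; adjusted p = 0.537 with an estimated correlation). Their within-slide medians ran from -2.32 to 2.21. Large single falls were the lipogenic regulator Thrsp (-2.16 ± 0.41), the glucocorticoid-induced Zbtb16 (-1.76 ± 0.32), Colq (-1.21), Asgr1 (-1.14), Thbs3 (-0.97) and Ecm2 (-0.95). With a slide term 1529 genes rose and 923 fell. Within slides 87.8% to 98.6% of called genes kept their sign, and 6.99% of genes had arrays that did not overlap, against 0.794% by chance. The count was 692 without STAT6 KO nanotube replicate 1, 1129 without replicate 4, and 741 with median centring, 94.3% of them rises in place of 65.9%. Median centring moved the median of all genes by 0.107 there.

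No gene's response differed between genotypes labelled day 28 in the limma test, where 1205 genes had an unadjusted p under 0.05. Ccl24 differed by -2.36 ± 0.72 (adjusted p = 0.566, and -2.98, adjusted p = 0.0902, without WT nanotube replicate 4) and Arg1 by -0.99 (adjusted p = 0.624). Camera called 9 lists and none of them held with an estimated correlation. Type 2 epithelium genes were lower in STAT6 KO (median -0.60, adjusted p = 0.32 with an estimated correlation). NK cell markers were higher by 0.51 (2 of 16 members adjusted over the list alone; adjusted p = 0.321 with an estimated correlation) and MHC II genes by 0.17 (adjusted p = 0.328 with an estimated correlation). Heart markers stood at -1.18 (adjusted p = 0.369 with an estimated correlation). IL-4/IL-13 macrophage genes, at -0.12, were not called (camera adjusted p = 0.0677). Leaving out WT nanotube replicate 4 or STAT6 KO nanotube replicate 5 gave 1 gene each, in the former case the retinal-oxidising enzyme Aldh1a3 (-1.64 ± 0.25, adjusted p = 0.00228; named after its value was seen). Across genes the responses correlated with r = 0.73 (jackknife SE 0.15), with 926 genes risen in both (169.4 for independent calls), 390 fallen in both (72.07 for independent calls) and none in opposite directions. Median centring moved the median of all genes by 0.151.

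**Figure D3:**
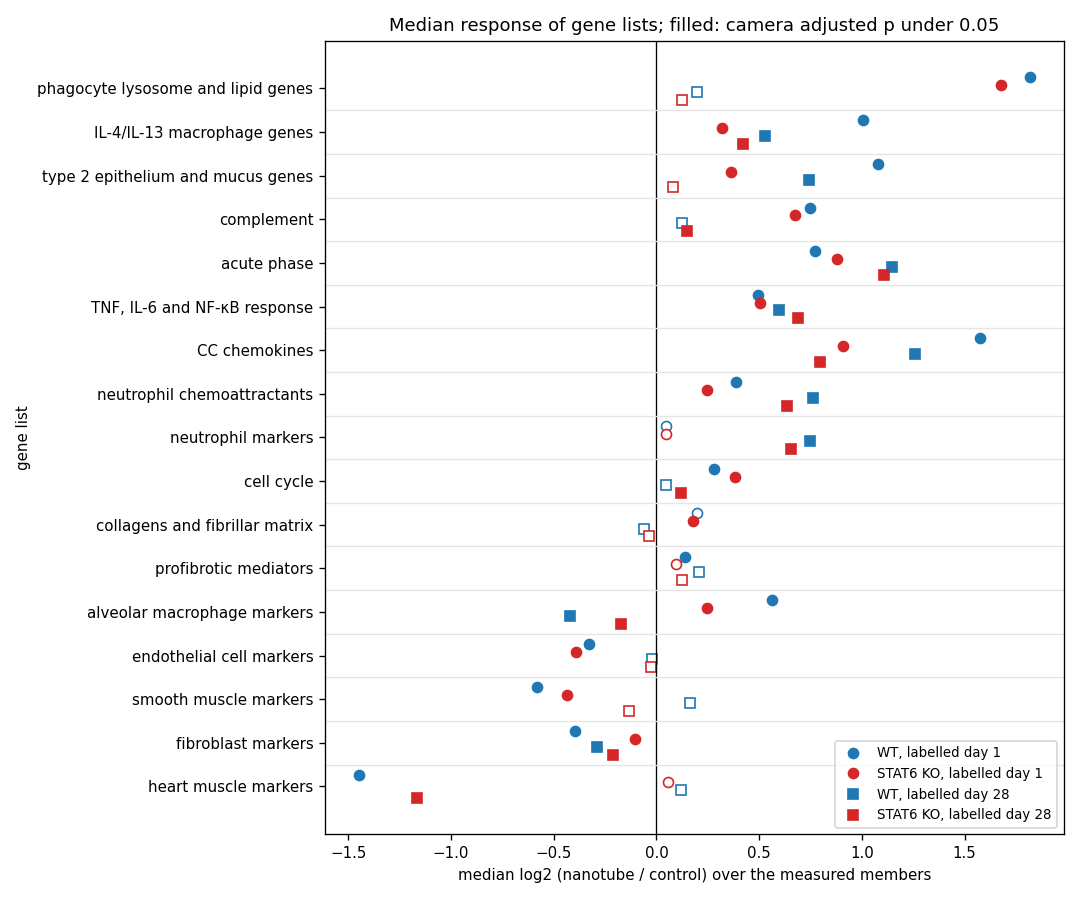
Median log2 change with nanotubes over the measured members of 17 gene lists (vertical axis) in each genotype and labelled day; filled symbols passed camera with its preset correlation. The lysosome list stood at 1.82 (WT) and 1.68 (STAT6 KO) labelled day 1 and at 0.20 and 0.12 labelled day 28, and neutrophil markers at 0.75 and 0.66 labelled day 28.

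The labelled days were compared through the signed difference of the responses within a genotype, so a response is also higher where a gene fell less. In WT the phagocyte genes rose less on the label day 28, namely Gpnmb (-4.28 ± 0.39), Trem2 (-4.13 ± 0.25), Spp1 (-3.22 ± 0.32) and Igf1 (-2.74). So did Chil3 (-3.57 ± 0.54), Chil4 (-2.97), Arg1 (-2.12) and Ccl11 (-1.12). Higher were the stress-induced Ankrd1 (2.35 ± 0.40), Saa2 (2.11 ± 0.61, with 1 of 5 controls above background on either day), the stromelysin Mmp3 (1.62), Pon1 (1.57) and the contractile genes Actg2 (1.76), Cnn1 (1.70) and Acta2 (1.05). Timp1 (1.75 ± 0.54) and Mt2 (1.64) were higher too, but no longer passed with a slide term (adjusted p = 0.0531 and 0.0663). The lysosome list was lower in 26 of 30 members (28 adjusted over the list alone; median -1.74), a call that held with an estimated correlation (adjusted p = 0.00448). Alveolar macrophage markers were lower in 14 of 20 (15 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation). Complement was lower in 13 of 20 (13 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation). Smooth muscle markers were higher in 7 of 13 (7 adjusted over the list alone; adjusted p = 0.275 with an estimated correlation) and endothelial markers in 7 of 23 (8 adjusted over the list alone; adjusted p = 0.406 with an estimated correlation). Neutrophil markers were higher in 8 of 22 (8 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation). Heart markers differed by a median of 1.34 (adjusted p = 0.723 with an estimated correlation), and the acute phase list, at 0.40, did not pass (camera adjusted p = 0.243). In total the response of 1379 genes was higher and that of 1576 lower on the label day 28 (1414 and 1685 with a slide term; same sign within slides for 98.6% to 99.1% of called genes). Median centring, which moved the median of all genes by -0.157, gave 929 genes, 6.35% of them higher in place of 46.7%. Some inflammatory genes did not pass with all arrays but did without nanotube replicate 4 labelled day 28. They were Saa3 (2.45, adjusted p = 0.00445), Ccl2 (1.86, 0.00381), Cxcl1 (2.15, 0.00147), Il6 (1.63, 0.012) and Il1b (1.41, 0.0356). Without replicate 5 Saa3 stood at 0.43 (adjusted p = 0.834).

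In STAT6 KO lung Trem2 (-3.90 ± 0.26), Gpnmb (-3.84 ± 0.41), Spp1 (-3.02), the lysosomal protease Ctss (-2.81) and Jchain (-2.44) had a lower response on the label day 28. Saa1 (2.85 ± 0.81), Cxcl1 (2.35 ± 0.71), S100a8 (2.28 ± 0.57), Ccl7 (2.23), Timp1 (1.93) and Il1b (1.78) had a higher one, as did the endothelial Esm1 (1.87), through its fall labelled day 1. The calls of Saa1, Cxcl1, Ccl7, Timp1 and Il1b were lost without some single arrays. The lysosome list was lower in 26 of 30 (28 adjusted over the list alone; median -1.48), and held with an estimated correlation (adjusted p = 0.0035). Alveolar macrophage markers were lower in 6 of 20 (9 adjusted over the list alone; adjusted p = 0.271 with an estimated correlation) and complement in 5 of 20 (10 adjusted over the list alone; adjusted p = 0.193 with an estimated correlation). Collagens were lower in 8 of 41 with 1 higher (9 and 1 adjusted over the list alone; adjusted p = 0.374 with an estimated correlation). B cell markers were higher in 2 of 18 (8 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation). Heart markers stood at -1.33 (adjusted p = 0.644 with an estimated correlation) and the acute phase list at 0.20 (camera adjusted p = 0.332). In total the response of 543 genes was higher and that of 611 lower (730 and 787 with a slide term; 97.8% to 99.5% same sign within slides), and median centring gave 207.

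Control lungs were compared to see how STAT6 KO and WT lung differ without nanotubes. Whether the loss of STAT6 gave the differences was not tested, and no fit included the time of day at which lungs were taken. Labelled day 1, 7 genes were higher and 18 lower in STAT6 KO (n = 4 and 5), and labelled day 28, 11 were higher and 11 lower (n = 5 and 5). With median centring 0 were higher and 6 lower labelled day 1, and 2 were higher and 9 lower labelled day 28. Among those found on both days were a higher Nab2, a repressor of early growth response factors (0.79 ± 0.09, adjusted p = 1.38e-05, and 0.98 ± 0.09, adjusted p = 1.13e-08). Lower on both days were H2-Q5, an MHC class I gene (-1.28 ± 0.21 and -1.22), and Nlrc5, a regulator of such genes (-1.12 and -0.82). The other kept probe of Nab2 and that of Nlrc5 moved the same way on both days, without an unadjusted limma p under 0.05. Dbp, an output gene of the circadian clock, was higher by 1.52 ± 0.31 (adjusted p = 0.0185) and 2.12 ± 0.29 (adjusted p = 0.000102), and labelled day 28 the clock repressors Nr1d1 (1.096) and Nr1d2 (0.77) were higher too. With median centring Nab2 (adjusted p = 0.139) and Dbp (0.181) no longer passed labelled day 1, nor Nr1d1 (0.124) and Nr1d2 (0.694) labelled day 28. Labelled day 1 the interferon-induced GTPase Igtp (-1.11) and the macrophage lectin Mgl2 (-0.80; adjusted p = 0.309 with median centring) were lower. Rnf41 was higher on both days (0.54 and 0.58), but the mean of its probes gave -0.247 and -0.159. Clca1 stood at 4.44 (SD 1.26) in WT and 0.33 (SD 0.22) in STAT6 KO controls labelled day 1 and did not pass (-4.11 ± 1.05, adjusted p = 0.125). Of the 4 STAT6 KO controls 1 was above background, and all lay below the WT controls (0.093 to 0.619 against 2.752 to 5.781). Its SE carries the wide spread of the WT groups labelled day 28 (SD 2.94 and 3.11).

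Among lists, interferon genes were lower labelled day 1 in 3 of 34 (8 adjusted over the list alone; median -0.22, adjusted p = 0.271 with an estimated correlation). Labelled day 28 none passed (3 adjusted over the list alone; median -0.09, adjusted p = 0.454 with an estimated correlation). Clock genes moved labelled day 28 in 3 rises and 1 fall of 18 (8 and 3 adjusted over the list alone; adjusted p = 0.193 with an estimated correlation). Labelled day 1 there was 1 rise (3 and 1 adjusted over the list alone; adjusted p = 0.193 with an estimated correlation). B cell markers stood lower at medians of -0.28 (adjusted p = 0.32 with an estimated correlation) and -0.17 (adjusted p = 0.454 with an estimated correlation). MHC II genes stood at -0.22 (adjusted p = 0.192 with an estimated correlation) and -0.19 (adjusted p = 0.271 with an estimated correlation). NK cell markers stood at -0.21 (adjusted p = 0.475 with an estimated correlation) and -0.24 (adjusted p = 0.434 with an estimated correlation). Heart markers differed by -1.41 (adjusted p = 0.282 with an estimated correlation) and 0.38 (adjusted p = 0.696 with an estimated correlation). Adipose markers differed by 0.29 labelled day 28 (adjusted p = 0.337 with an estimated correlation). With a slide term the counts were 6 and 15 labelled day 1, with 17 genes called in both fits, and 13 and 14 labelled day 28, with 20. Leaving out STAT6 KO control replicate 3 or replicate 4 gave 16 genes labelled day 1, WT control replicate 4 gave 39, and array weights gave 39 and 34 for the respective days.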

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

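The tests of slides, heart tissue, the single array and the neighbours of Stat6 were chosen after the result was seen; the test of the day labels and the counts of splits were not.

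The responses differed between the labelled days in 2955 genes in WT and 1154 in STAT6 KO by a test of the difference, with lysosome genes responding more under the label day 1 and acute-phase genes, whose list did not pass this test, under the label day 28. A slide batch and heart tissue are argued against for the lysosome part, since the score of nanotube arrays was lower under the label day 28 on each of the 5 slides that hold both (highest difference -1.111), and with a heart marker score as covariate the list medians were at most -1.331 and the score response differed by -1.661 ± 0.101 (SE). For the acute-phase part neither can be told apart, because the score response over both genotypes differed little beyond its spread even without a correction (0.515 ± 0.25, 95% interval from 0.004) and stayed about as large with a slide term (0.435 ± 0.265, from -0.111; within slides 0.274 to 1.079 on 4 and -0.114 on 1) and with the heart score (0.515 ± 0.254, from -0.006; list medians of at least 0.323). An exchange of the day labels could also give this order and cannot be told apart here. Collagen genes, whose expression falls as lungs mature, differed between controls labelled day 28 and day 1 by -0.039 in WT and -0.107 in STAT6 KO. The SD of their score between single arrays was 0.074 and 0.075, which is not the error of a difference of means. Unadjusted camera p was 0.974 in WT and 1.14e-05 in STAT6 KO (0.984 and 0.0142 with an estimated correlation). Of 41 members, 18 were above 0 in WT and 8 in STAT6 KO. The STAT6 KO values thus go against an exchange, while those of WT decide nothing. Cell cycle genes in the same controls were higher labelled day 28, by 0.088 in WT and 0.097 in STAT6 KO, both smaller than the SD between single arrays (0.177 and 0.18). Their unadjusted camera p was 0.019 and 0.000249, or 0.547 and 0.349 with an estimated correlation. A change of the response with time after instillation, which the design names, stays open as well and was not tested apart from the labels. The acute-phase values in WT depend on 1 array, nanotube replicate 4 labelled day 28. Its score was -0.379, against 0.67 to 1.779 on the others of its group. Without it the day difference of Saa3 went from 1.06 (limma adjusted p = 0.558) to 2.45 (0.00445).

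One WT nanotube array labelled day 28 (replicate 4) had a Saa3 value of -3.01, far from the other 4 arrays of its group (2.83 to 5.08). Over the genes called without it, the array lay at 0.415 of the way from the control mean to the mean of the other nanotube arrays, above all controls (-0.057 to 0.065), which argues against a control sample carrying a nanotube label. A swap with a control of the same day is argued against too, since no such control lay above 0.065, and so is a failed hybridisation, with 55.5% of its spots above background against 51.2% to 69.1% on the others. A smaller delivered dose may be a source of the weaker response and was not tested; without this array 2149 genes rose and 1757 fell in WT labelled day 28.

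Nab2, which lies next to Stat6 on the chromosome, was higher in STAT6 KO controls on both labelled days by its brightest probe. Its other kept probe moved the same way without an unadjusted limma p under 0.05. DNA of the donor strain around the deleted gene might make Nab2 higher. Among the 40 tested genes nearest to Stat6, 1 was called where 0.0893 were expected by chance (exact hypergeometric p = 0.0856, one-sided), which is too few to decide. Called genes farther from Stat6 on the same chromosome were not counted, so other linked genes may have been missed. The deletion itself could also change its neighbour, which was not tested.

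The responses of the genotypes differed labelled day 1 in 27 genes by a test of the difference. The score of the lysosome list was 1.67 in 1 of the 2 arrays that the labels place in no group, above the highest STAT6 KO control labelled day 1 (-0.48). Among 7896 features with no matched gene, 1292 changed with nanotubes in WT labelled day 1.

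Single arrays stood apart from the rest of their group for 13 of 176 gene and group pairs tested, where chance gives about 1 in 20 groups (8.8 here). Stat6 was 0.30 in a WT nanotube array labelled day 1 (others 0.67 to 0.79) and -0.02 in one labelled day 28 (others 0.45 to 0.64). Both lay on the same slide, where WT controls stood at 0.048 and 0.43 and STAT6 KO arrays between -0.936 and -0.428. Lcn2 was 1.12 in a WT control labelled day 1 (others 1.66 to 1.81) and 3 in a STAT6 KO nanotube array labelled day 28 (others 3.34 to 3.48). Arg1 was 1.07 in a STAT6 KO control and 2.55 in a STAT6 KO nanotube array labelled day 28 (others 0.60 to 0.69 and 1.19 to 1.47). Retnla was 4.63 in a WT control (others 4.95 to 5.07) and 5.41 in a STAT6 KO nanotube array (others 5.19 to 5.20), both labelled day 1. Muc5ac was 1.07 in a WT control labelled day 1 (others 0.66 to 0.75), and Hmox1 was -3.37 in a WT nanotube array labelled day 1 (others -0.69 to 0.08). In STAT6 KO nanotube arrays labelled day 28, 1 array had Clca1, above background on none of them, at -0.23 (others -0.03 to 0.03) and 1 had Spp1 at -2.60 (others -2.91 to -2.83).

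The arrays of each comparison were also split in other ways into groups of the same sizes. The real split was the only 1 of 100 splits to call as many genes for WT labelled day 1 (5219, highest other 2453) and day 28 (3444, 2187). The same held for STAT6 KO labelled day 28 (2072, 1041) and controls labelled day 28 (22, 3). It also held for the difference between days in WT (2955, 2080) and STAT6 KO (1154, 397). For STAT6 KO labelled day 1 the real split was the only 1 of 35 (2502, 16). Few random splits would thus call as many genes, but so few splits do not exclude chance. For the genotype difference labelled day 1 the real split was also the only 1 of 100, by a small margin (27, 25). For controls labelled day 1, 2 of 100 splits called as many, the real one with 25 and another with 30. For the genotype difference labelled day 28 the real count was 0, which any split reaches (100 of 100), so the splits decide nothing. The highest other split called 847, and the reason was not tested.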

How the results depend on the processing

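The alternatives without the doubted array and with the heart score were chosen after seeing the data. Every count of genes stayed above 0 under all alternatives except the genotype difference labelled day 28, but many counts moved. Median centring gave 2546 genes for WT and 835 for STAT6 KO labelled day 1, 752 and 741 labelled day 28, 6 and 11 for the controls, and 929 and 207 for the difference between days. Requiring a change of 1.5-fold, which only removes genes, left 1317, 830, 657 and 374 in the same order, 14 for controls labelled day 28, and 1108 and 629. Fits of the compared groups alone, with fewer arrays to estimate the spread, gave 564 for STAT6 KO labelled day 28 and 9 for controls labelled day 1. Array weights gave 1125 for STAT6 KO labelled day 28, 49 for the genotype difference labelled day 1, and 39 and 34 for the controls. The genotype difference labelled day 1 had 14 genes with Agilent processed signals and 16 with the strict dim filter, controls labelled day 28 had 14 with the mean of probes, and controls labelled day 1 had 16 with the heart score. The shared response labelled day 1 fell from 0.791 to 0.704 with Agilent processed signals and 0.724 with the Cy5 channel alone, and 5 of 168 list calls held with an estimated correlation. Of the 168 list calls 164 were kept with median centring and 129 with Agilent processed signals.

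Leaving out 1 array at a time, WT labelled day 28 ranged from 2261 (without nanotube replicate 5) to 3906 (without replicate 4), STAT6 KO labelled day 28 from 692 (without nanotube replicate 1; 1129 without replicate 4) to 2515, and controls labelled day 1 from 16 (without STAT6 KO replicate 3, and also without replicate 4) to 39 (without WT replicate 4). The genotype difference labelled day 28 ranged from 0 to 1 (without WT nanotube replicate 4, also the added alternative, or STAT6 KO nanotube replicate 5). The other counts stayed within 1.5 times: 4450 to 5120 for WT and 2017 to 2241 for STAT6 KO labelled day 1, 24 to 37 for the genotype difference, 16 to 22 for controls labelled day 28, and 2475 to 3085 and 897 to 1184 for the days.

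Some signs reversed. With the heart score, type 2 epithelium genes in controls labelled day 1 did so without passing (camera adjusted p = 0.47). Heart markers did so by construction, also without passing. This was in controls labelled day 1 (camera adjusted p = 0.794) and between days in STAT6 KO (camera adjusted p = 0.876). With Agilent processed signals the log2 change of Cidec went to 0.40 and 0.27 in WT labelled day 1 and 28. It went to 0.65 in STAT6 KO labelled day 28. Cyp4b1 went to 0.231 in STAT6 KO labelled day 1, and Cckar to -0.701 between days in WT. With the mean of probes Rnf41 went to -0.247 and -0.159 in controls. Except where the construction shows it, the cause was not tested. Of the named genes that passed, 79 of 103 kept their call under every alternative for WT labelled day 1, 62 of 91 for STAT6 KO, 53 of 77 and 42 of 72 labelled day 28, and 4 of 14 for the genotype difference labelled day 1. For controls 2 of 14 and 5 of 16 kept it, and between days 50 of 86 in WT and 27 of 68 in STAT6 KO. With about 55.7% of spots above background in the sample dye at the median array, changes of genes above background on no array of a compared group are limited to bounds. No paired analysis was possible because the labels pair no animals.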

Other observations

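Tests reported here use lists and comparisons fixed before the data were examined, except the count of all genes that differ between controls of the labelled days, which was added later.

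Further cell type lists moved with nanotubes in WT lung labelled day 1. Eosinophil markers rose in 6 of 12 with no fall (6 and 0 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation), led by the eosinophil ribonuclease Ear6 (2.17), and dendritic cell markers rose in 6 of 13 and fell in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation), with the transcription factor Batf3 at 1.19. Matrix proteases and inhibitors rose in 12 of 27 and fell in 5 (12 and 5 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation). Red blood cell markers fell in 8 of 9 (9 adjusted over the list alone; median -0.57, adjusted p = 0.192 with an estimated correlation), alveolar type 1 markers in 9 of 16 with 1 rise (9 and 1 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation), with the vessel growth factor Vegfa at -0.88, NK cell markers in 7 of 16 (7 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation) and ciliated cell markers in 5 of 22 (5 adjusted over the list alone; adjusted p = 0.525 with an estimated correlation). Oxidative stress and NRF2 genes went both ways, with 15 rises and 8 falls of 35 (16 and 10 adjusted over the list alone), and did not pass as a list (camera adjusted p = 0.0924); the phagocyte oxidase subunits Cyba (1.404) and Ncf1 (0.97) rose, while Hmox1, at 1.35 ± 0.58, did not pass (adjusted p = 0.0691) but did without nanotube replicate 4, its lowest array (1.97 ± 0.53, adjusted p = 0.00402).

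In STAT6 KO lung labelled day 1, red blood cell markers fell in 5 of 9 (6 adjusted over the list alone; adjusted p = 0.205 with an estimated correlation), and alveolar type 2 markers rose in 9 of 19 (9 adjusted over the list alone; adjusted p = 0.247 with an estimated correlation), with the fatty acid synthase Fasn at 0.80. Interferon genes rose in 6 of 34 (6 adjusted over the list alone; adjusted p = 0.686 with an estimated correlation), among them Cxcl9 (1.34). Labelled day 28 the clock activator Arntl fell with nanotubes in both genotypes (-0.90 in WT and -0.94 in STAT6 KO), and the clock list was called in neither.

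The 2 arrays that the labels place in no group had Stat6 at -0.262 and -0.215 and lysosome list scores of 1.67 and -0.528. Between controls labelled day 28 and day 1, 73 genes differed in WT and 0 in STAT6 KO in the limma test, where 2187 and 988 had an unadjusted p under 0.05.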
